A study of Homo sapiens with 12 samples.

How the data were processed

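Total RNA from 12 cultures of HCT116 cells, 3 per group, had been converted to biotin-labelled cRNA and hybridised to Illumina HumanHT-12 v4 bead arrays with 1 colour. The deposited probe signals are intensity values on a linear scale with no normalization across arrays, per the file headers and the values themselves. The detection p-value of each probe against the negative controls of its array is given beside it, per the file headers. The deposited log2 values have the same distribution on every array, and the normalization method is not given in the sources used here. They differed by at most 5e-06 from the log2 values computed here. The scanner software is not given in the sources used here either.

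The signals were normalized with the neqc method of limma 3.58.1 in R 4.3.3: background correction by a normal-exponential model with the negative-control mean and SD inferred from the detection p-values, an offset of 16, quantile normalization and log2 transformation. Of 47323 probes, 30113 carried 1 gene symbol in the platform's probe table, 8 carried several and 17202 were not named here and not used. The entrez gene identifiers of 30074 named probes were found in the reference gene table. A probe was kept if its detection p was under 0.05 on at least 3 of the 12 arrays, which left 15772 probes. Where a gene had several kept probes (3150 genes), the probe with the highest mean over the 12 arrays stood for it, so that 11785 genes were tested. No genome build is named for the probes, so no coordinates are given. Fold changes against a group in which no probe of the gene was detected on any array are printed as lower bounds ("at least").

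Groups were taken from the sample labels. A linear model with 1 mean per group was fitted to all 12 arrays with limma (lmFit and eBayes), and 5 differences of groups and the interaction were tested, two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. Errors printed after ± are standard errors of log2 fold changes unless SD is named, and n is 3 arrays per group. Gene lists, 22 in all, were tested with limma's camera with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists of a comparison. A list needed at least 5 measured genes, which 21 had. Counts for a list are given over all genes tested and adjusted over the list alone. The overlap of calls between comparisons was set beside the count for independent lists, and the correlation of fold changes beside 50 simulations of unchanged groups with each gene's own variance.

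The tests, the lists, the alternatives and the rule for naming genes were chosen before the data were examined, except where the text says otherwise. The rule names PPM1D and ATM in every comparison. It adds the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups do not overlap, or 5 and 5 for the combined comparison and, without the condition on overlap, for the interaction. From each list past its test it adds up to 4 members with the smallest adjusted p in the list's direction, and from the p53, DNA damage, pluripotency, DNA methylation and histone variant lists up to 3 otherwise. POU5F1, MACROH2A1, MACROH2A2, MYC, DNMT1, DNMT3A, DNMT3B, CDKN1A and MDM2 were to be named whatever their values. A few further list members are named with their values to fill out a list.

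The alternatives were other background corrections (normal-exponential with an offset of 50, or none), the deposited log2 values, equal array medians over all probes in place of quantile normalization, no or a stricter detection filter (detection p under 0.01 on all 3 arrays of a group), the mean of a gene's probes, array weights, the replicate number as a block, only the groups compared, a fold threshold of 1 on the log2 scale, and each array left out in turn. After the data were seen, 2 were added: equal array medians over the tested probes, and the number of detected probes per array as a covariate. Statements that a call was lost under a number of alternatives do not count the fold threshold.

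The procedure was tested on simulated data with the observed variances, in which 200 of 11785 genes were changed. It recovered 92% to 98% of changes of 1 on the log2 scale and 50% to 58% of changes of 0.5 in the differences of groups, and 88% and 13% in the interaction. Of the calls, 1.33% to 7.55% were false. A shifted list was recovered in all 6 comparisons with 0 of 20 unshifted lists called by camera. The simulated genes were drawn independently, so this does not show how often lists of correlated genes are called falsely.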

Results

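Gene expression was measured on Illumina bead arrays in HCT116, a human colorectal carcinoma cell line, in a design that crossed 2 factors. The first factor was depletion of Wip1 by a short hairpin RNA (Wip1SH) against the parental cells (WT). Wip1, encoded by PPM1D, is a phosphatase that is induced by p53 and removes phosphate groups from p53, ATM and other proteins of the DNA damage response. The second factor was an inhibitor of ATM (ATMi), the kinase that signals DNA double-strand breaks, given at 10 µM for 3 days with daily renewal. The 4 groups (WT, WT+ATMi, Wip1SH and Wip1SH+ATMi) had 3 arrays each, from RNA that the series' design text describes as biological replicates. No control hairpin is among the 4 groups. Changes on depletion named below therefore compare Wip1SH with parental cells and include any other difference between them. The sample labels name no vehicle for the groups without the inhibitor. Changes credited to the inhibitor can therefore include effects of its solvent or of the daily renewal. The design asks which genes differ between the parental and the Wip1-depleted cells and how inhibition of ATM changes expression in each.

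Array brightness moved with the groups. The mean signal per array was 524 ± 10.5 (SD, n = 3) in WT, 613 ± 61.7 in Wip1SH, 689 ± 31.5 in WT+ATMi and 694 ± 48.9 in Wip1SH+ATMi. Between 17650 and 17929 probes were detected on the WT arrays, 18568 to 18961 on the Wip1SH arrays, 18723 to 19654 on the WT+ATMi arrays and 19505 to 20408 on the Wip1SH+ATMi arrays. After normalization, the correlation between arrays across the 11785 genes tested was 0.991 to 0.995 within groups and 0.976 to 0.988 between groups. The number of arrays limits the precision of each value, and the median standard error of a log2 fold change was 0.11 for a difference of 2 groups and 0.15 for the interaction.

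PPM1D, the target of the hairpin, was lower on every Wip1SH array than on every WT array. Its normalized log2 intensity was 10.34 ± 0.08 (SD, n = 3) in WT, 10.64 ± 0.04 in WT+ATMi, 8.68 ± 0.22 in Wip1SH and 8.79 ± 0.09 in Wip1SH+ATMi. The transcript was 3.17-fold lower in Wip1SH than in WT (log2 fold change -1.66 ± 0.10, SE; adjusted p = 2.57e-06) and was also lower in Wip1SH+ATMi than in WT+ATMi (-1.85 ± 0.10, adjusted p = 6.37e-07). The inhibitor left PPM1D without a difference past the threshold in WT (log2 fold change 0.30 ± 0.10, adjusted p = 0.0568) and in Wip1SH (0.11 ± 0.10, adjusted p = 0.486). The ATM transcript passed the threshold in none of the 5 comparisons of groups, with adjusted p-values of 0.0645 to 0.963. Its log2 fold change was 0.18 ± 0.17 for Wip1SH against WT, where the other detected ATM probe, which was not tested, was at -0.09. For WT+ATMi against WT the tested probe was at 0.48 and the other at 0.42. For Wip1SH+ATMi against Wip1SH they were at -0.02 and 0.14. Under the inhibitor, Wip1SH+ATMi against WT+ATMi gave -0.31 and -0.37.

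**Figure D1:**
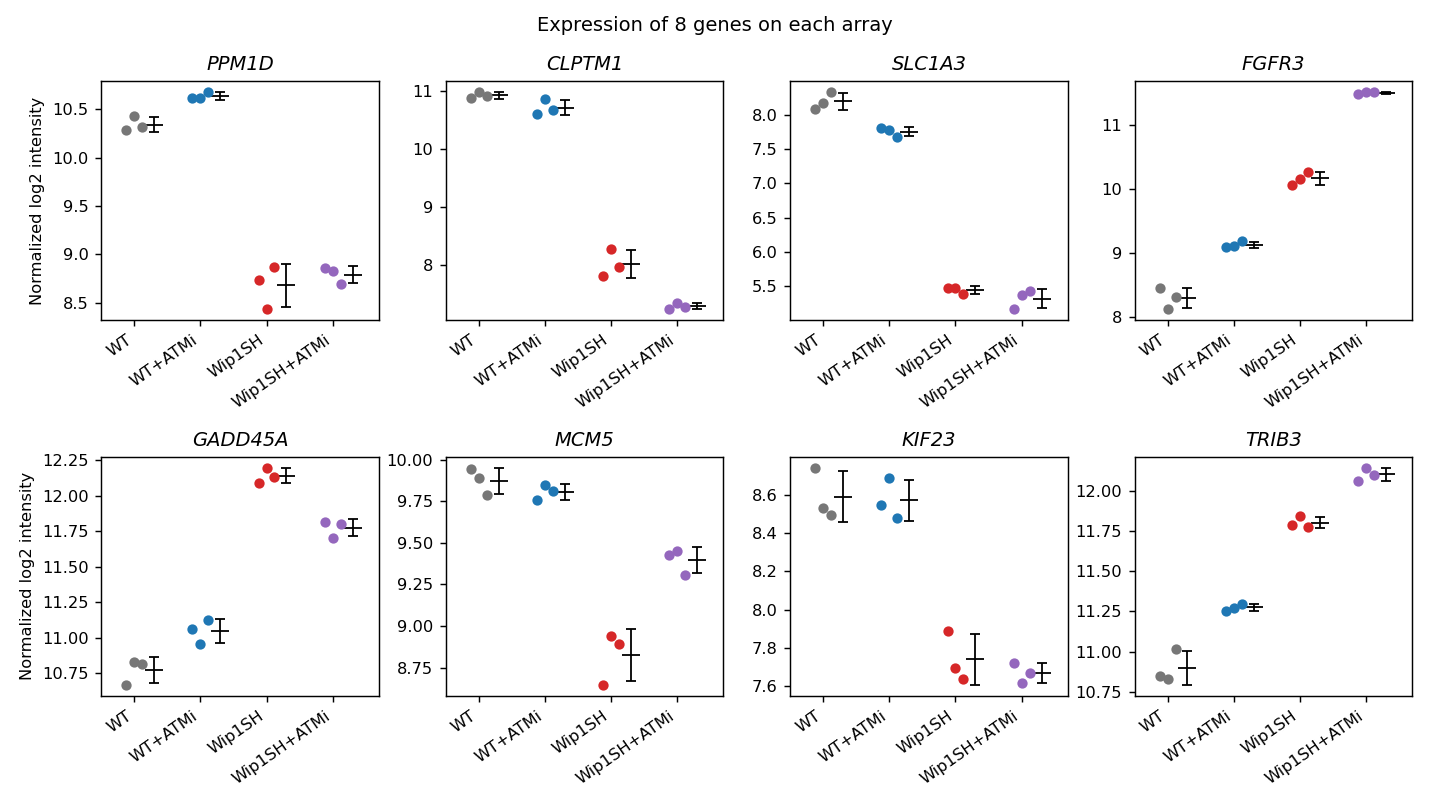
Normalized log2 intensity (vertical axis, each panel with its own range) of 8 genes on each of the 12 arrays. Points are arrays, and the horizontal bars with whiskers are the mean and SD of 3 arrays per group. PPM1D, CLPTM1 and SLC1A3 were low in both Wip1-depleted groups, where PPM1D averaged 8.68 and 8.79, and FGFR3 was highest in Wip1SH+ATMi at 11.51.

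In Wip1SH against WT, without the inhibitor, p53 target genes and genes of the amino acid and endoplasmic reticulum stress response were higher. Genes of DNA replication and mitosis were lower. Of 11785 genes, 1976 were higher and 1818 lower in Wip1SH than in WT, and 115 of them differed at least 2-fold. The median size of a called change was 0.44 on the log2 scale. Most called changes were therefore smaller than that of PPM1D, but 6 genes had a fitted fold change below that of PPM1D.

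These 6 genes were CLPTM1, SLC1A3, SUSD2, IL32, TESC and VSNL1. CLPTM1, which encodes a membrane protein, had the lowest fold change, -2.92 ± 0.11 (SE; adjusted p = 6.01e-08), from a log2 intensity of 10.93 in WT to 8.01 in Wip1SH. SLC1A3, a glutamate transporter, was not well above background on any Wip1SH array and was at least 6.30-fold lower than in WT. IL32, a cytokine gene, was likewise not well above background in Wip1SH and was at least 2.89-fold lower, a bound that does not reach the 3.17-fold of PPM1D. SUSD2 fell by 2.14 ± 0.10, TESC, which encodes a calcium-binding protein, by 1.80 ± 0.10, and VSNL1, a neuronal calcium sensor, by 1.68 ± 0.14, which is within its standard error of PPM1D. The other detected VSNL1 probe, which was not tested, was at -1.38, a smaller fall than that of PPM1D. SNRNP35, a component of the minor spliceosome, was at least 2.63-fold lower, CEMIP, involved in hyaluronan breakdown, at least 1.91-fold lower, and KRTAP3-1 fell by 1.60 ± 0.16. In the other direction, the small nucleolar RNA SNORA71C was at least 3.17-fold higher, since it was not well above background in WT. FGFR3, a fibroblast growth factor receptor, rose by 1.88 ± 0.09 (adjusted p = 3.2e-07). ARL14 rose by 1.80 ± 0.18, although only 1 of the 3 WT arrays detected it. CREBRF, EGR1, SNAI2, MSX2, ARRDC4, DKFZP586I1420 and the cholesterol exporter gene ABCA1 followed, with log2 fold changes of 1.37 to 1.60. EGR1 is an immediate-early transcription factor and SNAI2 (Slug) a repressor of epithelial genes. The genes named for their fold change were chosen among those with all 3 arrays of one group above all 3 of the other, a separation that chance alone gives in 10% of genes.

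Among 32 measured p53 targets, 15 rose and none fell (18 rose when adjusted over the list alone), with a median log2 fold change of 0.35 and an adjusted p of 5.25e-06 for the list. GADD45A, which acts in growth arrest after DNA damage, rose by 1.37 ± 0.08 (adjusted p = 8.78e-07). PHLDA3 rose by 0.76 ± 0.09, TP53INP1 by 0.72 ± 0.09 and SESN1, a stress-induced sestrin, by 0.67 ± 0.08. The brighter of the 2 probes of CDKN1A, the p21 cell cycle inhibitor, lay near the top of the scale at 14.83 in WT and did not pass the threshold (log2 fold change 0.05 ± 0.08, adjusted p = 0.672). The dimmer CDKN1A probe, at 7.84 in WT, had a fold change of 0.58. MDM2, which encodes the ubiquitin ligase of p53, had a fold change of -0.11 ± 0.16 (adjusted p = 0.614).

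DNA replication genes fell, 17 of 30 with none higher (20 fell when adjusted over the list alone; median -0.46, adjusted p = 3.43e-09). GINS3 fell by 1.38 ± 0.12, the helicase subunit genes MCM5 by 1.05 ± 0.09 and MCM3 by 0.60 ± 0.07, and RFC5, a clamp loader subunit, by 0.70 ± 0.07. Of 35 mitosis genes, 28 fell and none rose (29 fell when adjusted over the list alone; median -0.39, adjusted p = 2.94e-13). KIF20A fell by 0.97 ± 0.11, CDC20 by 0.92 ± 0.09, KIF23 by 0.85 ± 0.10 and KIF2C by 0.66 ± 0.07. MYC-responsive growth genes fell as well (9 lower and 1 higher of 25, the same when adjusted over the list alone; median -0.16, adjusted p = 0.0011), among them CAD, FBL, TFRC and SRM, with fold changes of -0.66 to -0.62. MYC itself fell by 0.34 ± 0.09 (adjusted p = 0.0112). With array medians set equal over all probes, which moved the median of the tested genes to 0.24, the medians were -0.20 for DNA replication, -0.11 for mitosis and 0.04 for the MYC-responsive list, and the MYC call was lost.

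Of 26 genes of the ATF4 and unfolded protein response, 17 rose and 3 fell (19 and 3 when adjusted over the list alone; median 0.37, adjusted p = 4.94e-07). DDIT3 (CHOP) rose by 1.29 ± 0.11, PPP1R15A by 1.07 ± 0.09, TRIB3 by 0.90 ± 0.07 and STC2 by 0.72 ± 0.06. Wnt targets and intestinal stem cell markers fell by the preset test (6 of 12 lower, or 6 lower and 1 higher when adjusted over the list alone; adjusted p = 0.011), with adjusted p = 0.111 with an estimated correlation. RNF43 fell by 1.01 ± 0.12, AXIN2 by 0.69 ± 0.10 and DKK1 by 0.60 ± 0.08, and NOTUM was at least 1.20-fold lower. NRF2 targets, which serve the oxidative stress response, had 7 genes higher and 3 lower of 15 (8 and 3 when adjusted over the list alone). Their adjusted p was 0.0439, with adjusted p = 0.11 with an estimated correlation, and 0.0567 to 0.0715 without WT replicate 2 or 3, Wip1SH replicate 1 or 2, or Wip1SH+ATMi replicate 2. With the replicate number as a block it was 0.0666, and over all alternatives 0.00853 to 0.216, with the call lost under 13 of 24. In this list HMOX1 rose by 0.98 ± 0.07, AKR1B10 by 0.81 ± 0.07, ABCC3 by 0.37 ± 0.07 and NQO1 by 0.31 ± 0.07.

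Genes of DNA damage signalling and repair did not move as a list (4 of 19 lower, also when adjusted over the list alone; adjusted p = 0.37), although CHEK1 fell by 0.49 ± 0.10 and BLM by 0.50 ± 0.12. The DNA methylation list (4 lower and 1 higher of 11, or 6 and 1 when adjusted over the list alone; adjusted p = 0.0633, and 0.0367 without the detection filter and 0.0396 without Wip1SH replicate 2) contained UHRF1, which fell by 0.87 ± 0.08, MBD4, by 0.62 ± 0.10, DNMT1, the maintenance methyltransferase, by 0.41 ± 0.07, and DNMT3B, by 0.38 ± 0.08. Histone variant and Polycomb genes did not move as a list (5 lower and 2 higher of 20, also when adjusted over the list alone; adjusted p = 0.302), and within it CBX2 fell by 1.00 ± 0.10, ASF1B by 0.83 ± 0.10 and H3-3B by 0.42 ± 0.07. MACROH2A1 and MACROH2A2, which encode the macroH2A histone variants, had fold changes of -0.01 ± 0.07 (adjusted p = 0.929) and -0.15 ± 0.07 (adjusted p = 0.12), and the other detected MACROH2A1 probes pointed upward at 0.25 and 0.26. Of the pluripotency genes only 3 were measured. KLF4 rose by 0.76 ± 0.08 and PODXL fell by 0.49 ± 0.09. POU5F1 (OCT4) was above background by 1 probe on 1 of the 12 arrays and DNMT3A on none, so neither was tested.

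With array medians equal over all probes, the calls split into 3826 higher and 342 lower genes, and with the number of detected probes per array as a covariate 886 genes passed. Of the 61 named genes past the threshold, 9 lost their call under the first of these settings and 8 under the second.

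**Figure D2:**
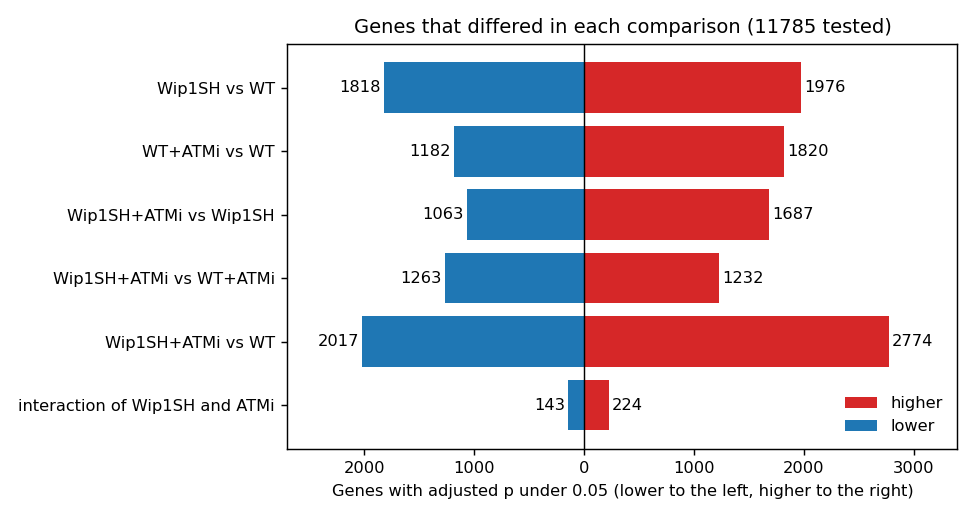
Number of genes with an adjusted p under 0.05 in each comparison, higher to the right and lower to the left of 0 on the horizontal axis. The combined comparison had the most, 2774 higher and 2017 lower, and the interaction the fewest, 224 and 143.

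In WT cells, the inhibitor raised single genes of the oxidative stress response and lowered SNAI2, while the p53 target list did not shift. Of 11785 genes, 1820 were higher and 1182 lower in WT+ATMi than in WT, and 97 differed at least 2-fold. FCGBP rose by 1.73 ± 0.11 (SE; adjusted p = 7.74e-06), the immediate-early gene FOS by 1.72 ± 0.19 (adjusted p = 2e-04), ABTB1 by 1.65 ± 0.16, SHROOM2 by 1.56 ± 0.13 and TSKU, a secreted leucine-rich protein gene, by 1.55 ± 0.10. LEMD1 rose 2.82-fold, and LINC02035 and TMEM8B had log2 fold changes of 1.45 and 1.41, although the other detected TMEM8B probe pointed downward at -0.23. PRDM16 and the kinase gene RPS6KA2 were not well above background in WT and were at least 2.11-fold and 2.22-fold higher. CPA4, a carboxypeptidase gene, fell by 1.64 ± 0.10 (adjusted p = 6.87e-06). KRT34, SNAR-A1, NRG1, HLA-DRB4, SNORA12, DUSP5, TMEM40, PDGFB and MYL9 fell, with log2 fold changes of -1.38 to -1.19. NRG1 encodes a ligand of ERBB receptors, PDGFB a growth factor and DUSP5 a phosphatase of ERK, and the other detected HLA-DRB4 probe was at 0.07.

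The p53 targets went both ways (6 higher and 7 lower of 32, or 10 and 7 when adjusted over the list alone; median 0.03, adjusted p = 0.859, with a downward direction in the test). GDF15 rose by 0.89 ± 0.10, while SFN (14-3-3 sigma) fell by 0.59 ± 0.08 and ZMAT3 by 0.51 ± 0.08, although 1 other detected ZMAT3 probe pointed upward at 0.52. MDM2 fell by 0.50 ± 0.16 (adjusted p = 0.0361), a call lost under 9 of 24 alternatives (without WT replicate 3 or any WT+ATMi array among them), and the brighter CDKN1A probe rose by 0.26 ± 0.08 (adjusted p = 0.0311), lost under 8 (without WT replicates 1 or 2 or WT+ATMi replicates 1 or 3 among them), while the dimmer one was at -0.03. Neither DNA replication (1 higher of 30, adjusted p = 0.602) nor mitosis genes (1 higher and 3 lower of 35, adjusted p = 0.602) moved as a list, with the same counts when adjusted over the list alone.

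By the preset test, 5 lists passed in this comparison, and none of them did with an estimated correlation. NRF2 targets rose (7 higher and 1 lower of 15, also when adjusted over the list alone; adjusted p = 0.00682, and adjusted p = 0.0594 with an estimated correlation), with AKR1C3 up by 1.33 ± 0.18, ABCC3 by 1.28 ± 0.07, NQO1 by 1.14 ± 0.07 and HMOX1 by 1.06 ± 0.07. Cholesterol and fatty acid synthesis genes rose (7 of 17, 9 when adjusted over the list alone; adjusted p = 0.00977, and adjusted p = 0.0594 with an estimated correlation), among them INSIG1 by 0.75 ± 0.11, SCD by 0.50 ± 0.08 and FASN by 0.40 ± 0.08. Aryl hydrocarbon receptor targets rose (3 of 6, also when adjusted over the list alone; adjusted p = 0.0208, and adjusted p = 0.0862 with an estimated correlation), namely NQO1, TIPARP by 0.50 ± 0.09 and CYP1B1 by 0.33 ± 0.10 (a call lost without any 1 of WT replicates 2 and 3 and WT+ATMi replicates 1 and 2), and with equal array medians over the tested probes this list had an adjusted p of 0.0521. Mesenchymal and matrix genes fell (3 of 10, 5 when adjusted over the list alone; adjusted p = 0.00682, and adjusted p = 0.0594 with an estimated correlation), with SNAI2 down by 1.06 ± 0.12, THBS1 by 0.87 ± 0.10 and CCN1 by 0.52 ± 0.09. MYC-responsive growth genes fell (6 lower and 1 higher of 25, or 7 and 1 when adjusted over the list alone; adjusted p = 0.0173, and adjusted p = 0.0594 with an estimated correlation), as did MYC, by 0.32 ± 0.09, a call lost without WT replicate 1 and without WT+ATMi replicate 2. With array medians equal over all probes, which moved the median of the tested genes to 0.43, the medians of the mesenchymal and MYC-responsive lists were 0.13 and 0.30.

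Chromatin genes moved singly. MACROH2A2 rose by 0.43 ± 0.07 (adjusted p = 0.00124) and ASF1B by 0.57 ± 0.10, while DAXX fell by 0.37 ± 0.07. MACROH2A1 fell by 0.23 ± 0.07 (adjusted p = 0.0432), a call lost under 13 of 24 alternatives, among them every left-out array except WT replicate 1, Wip1SH replicate 2 and Wip1SH+ATMi replicates 1 and 2. MBD4 fell by 0.50 ± 0.10, TDG by 0.43 ± 0.10, DNMT3B by 0.30 ± 0.08 and UHRF1 by 0.29 ± 0.08, the DNMT3B call being lost under 5 alternatives (without WT replicate 3 and WT+ATMi replicates 1 and 3 among them) and the UHRF1 call under 4 (without WT replicates 1 and 2 among them). DNMT1 had a fold change of 0.11 ± 0.07 (adjusted p = 0.308). Neither the DNA methylation list (5 lower and 1 higher of 11, also when adjusted over the list alone; adjusted p = 0.081, and 0.0367 with the mean of probes) nor the histone variant and Polycomb list (7 higher and 3 lower of 20, or 8 and 3 when adjusted over the list alone; adjusted p = 0.475) passed. The repair genes PRKDC and BARD1 rose by 0.58 ± 0.10 and 0.59 ± 0.12, and PODXL by 0.41 ± 0.09.

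The excess of higher over lower genes followed the normalization: 1457 genes were higher and 1923 lower with array medians equal over the tested probes, and 7041 and 165 with medians equal over all probes. With the number of detected probes as a covariate 33 genes passed, and 43 of the 55 named genes past the threshold lost their call.

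In Wip1-depleted cells, the inhibitor lowered p53 targets and raised DNA replication genes as lists, opposite to the list shifts seen on depletion. The mitosis genes did not shift. Of 11785 genes, 1687 were higher and 1063 lower in Wip1SH+ATMi than in Wip1SH, and 66 differed at least 2-fold. Of 32 p53 targets, 11 fell and 2 rose (12 and 2 when adjusted over the list alone; median -0.23, adjusted p = 0.000237). With array medians equal over all probes, which moved the median of the tested genes to 0.15, the median of the p53 targets was -0.04. SFN fell by 0.98 ± 0.08 (SE; adjusted p = 3.87e-05), TP53I3 by 0.65 ± 0.09, PLK2 by 0.52 ± 0.10 and GADD45A by 0.37 ± 0.08. The dimmer CDKN1A probe was at -0.62, and the brighter one at -0.03 ± 0.08 (adjusted p = 0.824). Of 30 DNA replication genes, 15 rose and none fell (16 rose when adjusted over the list alone; median 0.37, adjusted p = 3.47e-06), among them GINS2 by 0.67 ± 0.09, MCM3 by 0.55 ± 0.07, CDC45 by 0.53 ± 0.08 and MCM7 by 0.50 ± 0.06. Of 35 mitosis genes, 3 rose and 3 fell (2 and 3 when adjusted over the list alone; median 0.04, adjusted p = 0.971, with a downward direction in the test). MYC-responsive growth genes had 8 lower and 1 higher of 25 (9 and 3 when adjusted over the list alone; median -0.13, 0.03 with array medians equal over all probes), among them RRP9, which fell by 0.71 ± 0.16, and WDR12, which fell by 0.35 ± 0.09. That list had an adjusted p of 0.0439, with adjusted p = 0.112 with an estimated correlation, and 0.0557, 0.0794 and 0.091 without Wip1SH replicate 1, Wip1SH replicate 3 and Wip1SH+ATMi replicate 3.

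Among single genes, RNA18SN5, an 18S ribosomal RNA gene, rose by 1.77 ± 0.18 (SE; adjusted p = 0.000128), LFNG, a glycosyltransferase of Notch signalling, by 1.61 ± 0.16, the interferon regulatory factor IRF1 by 1.61 ± 0.18 and TSKU by 1.49 ± 0.10. TSPAN18, TUBB3, FGFR3, OPN3, ABCC3 and ESAM rose by 1.28 to 1.43, although the other detected FGFR3 probe pointed downward at -0.58. MTF1, a metal-responsive transcription factor gene, fell by 1.56 ± 0.12 (adjusted p = 3.15e-05), and AKR1B15, MYH16, SNAI2, WFDC2 and AKR1B10 fell, with fold changes of -1.55 to -1.51. CPA4 fell by 1.49 ± 0.10, and TRIM16L, CDC42BPB and ARRDC4 had fold changes of -1.35 to -1.33. MACROH2A2 rose by 0.46 ± 0.07 (adjusted p = 0.00105), CBX2 by 0.78 ± 0.10 and ASF1B by 0.77 ± 0.10. In the DNA methylation list, MBD4 rose by 0.37 ± 0.10, HELLS rose by 0.33 ± 0.10 and MBD1 fell by 0.45 ± 0.11. The MBD4 call was lost without Wip1SH replicates 1 or 2 or Wip1SH+ATMi replicates 2 or 3, the HELLS call without Wip1SH replicates 1 or 2 or Wip1SH+ATMi replicates 1 or 2, and the MBD1 call without Wip1SH+ATMi replicates 2 or 3. BARD1 rose by 0.68 ± 0.12 and H2AX fell by 0.67 ± 0.15. PRKDC rose by 0.48 ± 0.10, but its other 3 detected probes pointed downward. Values short of the threshold were MACROH2A1 at -0.08 ± 0.07 (adjusted p = 0.471), MYC at -0.24 ± 0.09 (adjusted p = 0.0613), DNMT1 at 0.16 ± 0.07 (adjusted p = 0.136), DNMT3B at 0.24 ± 0.08 (adjusted p = 0.0563) and MDM2 at -0.43 ± 0.16 (adjusted p = 0.0701). Dimmer detected probes, which were not tested, were at -0.56 for MYC and at -0.55 and -0.05 for MACROH2A1.

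The genes changed by depletion and changed back by the inhibitor numbered 792, or 20.9% of the 3794 called in Wip1SH against WT. Of these, 259 had risen on depletion and 533 had fallen, and a further 343 genes moved on in the same direction under the inhibitor. Among the 17 DNA replication genes that had fallen, 13 rose again (CDC45, CDT1, CHAF1A, CHAF1B, GINS2, MCM2, MCM3, MCM5, MCM6, MCM7, POLE, RFC5 and UNG), and 4 of the 15 p53 targets that had risen fell again (DRAM1, GADD45A, SESN2 and TP53INP1). Of the 28 mitosis genes that had fallen, 3 rose again. Both comparisons contain the Wip1SH arrays, so chance values on those arrays enter both with opposite sign. Independent lists would share 178 genes that rose and 260 that fell. Across genes, which are not independent replicates, the fold changes of the 2 comparisons correlated at r = -0.21, against -0.50 in 50 simulations of unchanged groups that shared these arrays. Their covariance was -0.0221, against -0.00889 from shared arrays alone, a difference of -0.0132. The 3 shared arrays are too few to be divided, and part of the excess can come from them. The inhibitor's effects in WT and Wip1SH also correlated (r = 0.54), and the simulated groups had no such shared effect. A gene can therefore change back without a difference between the genotypes. The interaction passed in 367 genes, and in 3 of the 30 DNA replication genes (12 when adjusted over the list alone). Without Wip1SH replicate 1 the count was 517, with array medians equal over all probes 264, and with detected probes as a covariate 30.

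In this comparison the calls split into 2096 higher and 285 lower genes with array medians equal over all probes, and 159 genes passed with the covariate. Under that covariate 20 of the 41 named genes past the threshold lost their call.

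**Figure D3:**
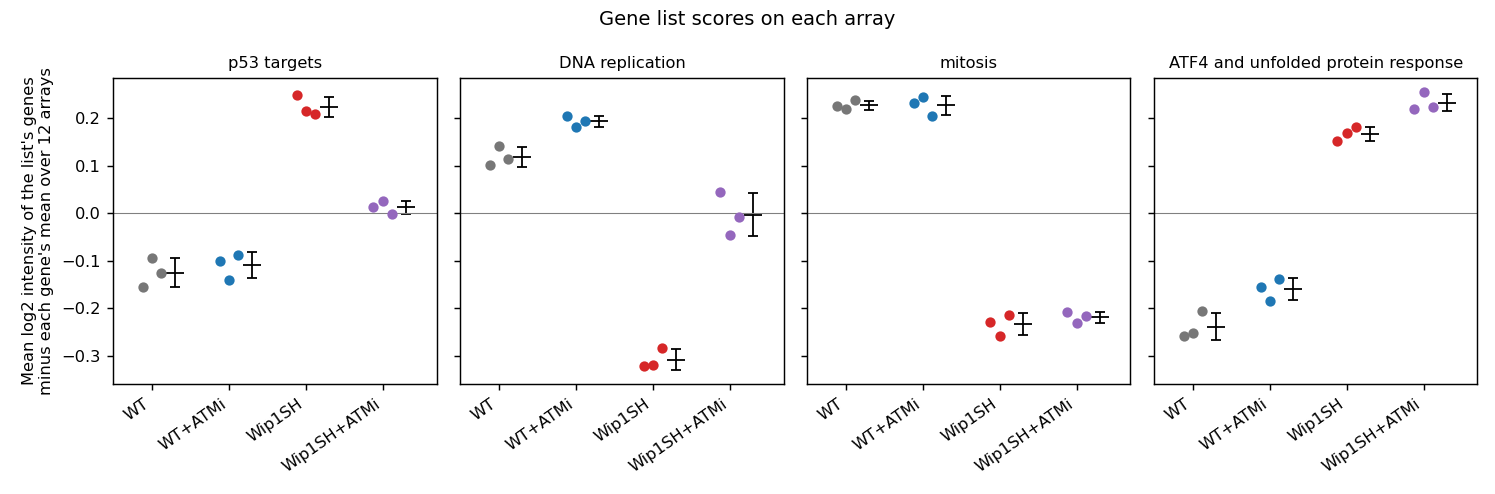
Score of 4 gene lists on each array: the mean over the list's genes of the log2 intensity minus each gene's mean over 12 arrays (vertical axis, shared). Points are arrays, and bars with whiskers are the mean and SD of 3 arrays. The p53 target score was 0.22 in Wip1SH and 0.01 in Wip1SH+ATMi, while the mitosis score was -0.23 and -0.22.

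Under the inhibitor, Wip1-depleted cells still had lower mitosis genes and higher ATF4 and unfolded protein response genes than WT cells, and lower Wnt target and cholesterol synthesis genes. Of 11785 genes, 1232 were higher and 1263 lower in Wip1SH+ATMi than in WT+ATMi, and 85 differed at least 2-fold. Mitosis genes fell (26 of 35, 30 when adjusted over the list alone; median -0.45, adjusted p = 1.61e-15), with KIF23 down by 0.90 ± 0.10 (SE), KIF20A by 0.85 ± 0.11, the kinase genes NEK2 by 0.70 ± 0.09 and AURKB by 0.61 ± 0.08. DNA replication genes fell in 6 of 30 cases (also when adjusted over the list alone; median -0.16, adjusted p = 0.000566), with GINS3 down by 1.33 ± 0.12, MCM5 by 0.41 ± 0.09 and MCM4 by 0.38 ± 0.09. Genes of the ATF4 and unfolded protein response rose (17 higher and 1 lower of 26, or 19 and 2 when adjusted over the list alone; median 0.40, adjusted p = 3.06e-09), with DDIT3 up by 1.11 ± 0.11, PPP1R15A by 0.97 ± 0.09, TRIB3 by 0.83 ± 0.07 and STC2 by 0.63 ± 0.06.

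Wnt targets and intestinal stem cell markers fell (9 of 12, 10 when adjusted over the list alone; median -0.60, adjusted p = 3.15e-08). NOTUM fell by 1.08 ± 0.12, AXIN2, a feedback inhibitor of Wnt signalling, by 1.03 ± 0.10 and DKK1 by 0.83 ± 0.08, and NKD1 was at least 1.25-fold lower. Cholesterol and fatty acid synthesis genes fell (10 lower and 1 higher of 17, or 12 and 1 when adjusted over the list alone; median -0.37, adjusted p = 0.000437), with FASN down by 0.75 ± 0.08, HMGCS1 by 0.59 ± 0.12, INSIG1 by 0.57 ± 0.11 and SCD by 0.36 ± 0.08. MYC-responsive growth genes fell (8 of 25, or 8 lower and 1 higher when adjusted over the list alone; median -0.20, adjusted p = 0.000236), with RRP9 down by 0.76 ± 0.16, TFRC by 0.52 ± 0.09, BOP1 by 0.46 ± 0.08 and FBL by 0.44 ± 0.09. The 10 control genes also passed (2 lower, GAPDH by 0.25 ± 0.07 and B2M by 0.23 ± 0.07, and 4 lower when adjusted over the list alone; median -0.16, adjusted p = 0.0326), the GAPDH and B2M calls being lost under 10 and 15 of 24 alternatives. The GAPDH call was lost without any array of these groups except Wip1SH+ATMi replicate 3, and the B2M call without any of them or Wip1SH replicates 1 or 2. The list had adjusted p = 0.134 with an estimated correlation, and 0.0515 to 0.0821 without WT+ATMi replicate 1, Wip1SH+ATMi replicate 1 or Wip1SH+ATMi replicate 2. The p53 targets did not pass (11 higher and 4 lower of 32, or 11 and 5 when adjusted over the list alone; median 0.09, adjusted p = 0.103, and 0.0158 without the detection filter). Within them GADD45A rose by 0.73 ± 0.08 and TP53I3 fell by 0.70 ± 0.09. ZMAT3 rose by 0.66 ± 0.08, but its other 2 detected probes pointed downward.

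The largest falls were again those of CLPTM1 (-3.44 ± 0.11, SE; adjusted p = 1.09e-08) and SLC1A3 (-2.44 ± 0.09, with 1 of the 3 Wip1SH+ATMi arrays above background). CEMIP, CHPF, TESC, SUSD2, CDK6 and VSNL1 had fold changes of -2.29 to -1.78, and the cell cycle kinase gene CDK6 was among them at -1.90 ± 0.09. SCARA3 was at least 2.31-fold lower. SNORA71C was at least 4.57-fold higher and ARL14 at least 2.20-fold higher, both being not well above background in WT+ATMi. FGFR3 rose by 2.39 ± 0.09 by its brighter probe, while the dimmer one was at -0.52. SUN3, TAOK1, LURAP1L, DUSP5, DKFZP586I1420, HSPA13 and OR2A9P rose by 1.12 to 1.42. PODXL fell by 0.93 ± 0.09, KLF4 rose by 0.71 ± 0.08, and H3-3B fell by 0.70 ± 0.07, ASF1B by 0.63 ± 0.10, CBX2 by 0.49 ± 0.10, CHEK1 by 0.53 ± 0.10 and DNMT1 by 0.36 ± 0.07. UHRF1 fell by 0.33 ± 0.08. CDKN1A fell by 0.24 ± 0.08 (adjusted p = 0.0477), a call lost under 18 of 24 alternatives, among them every left-out array except WT+ATMi replicate 2, and the dimmer CDKN1A probe was at -0.01. MACROH2A1 (0.13 ± 0.07, adjusted p = 0.229), MACROH2A2 (-0.12 ± 0.07, adjusted p = 0.23), MYC (-0.26 ± 0.09, adjusted p = 0.0519, with the dimmer probe at -0.35), DNMT3B (0.16 ± 0.08, adjusted p = 0.205) and MDM2 (-0.04 ± 0.16, adjusted p = 0.889) did not pass.

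The effect of depletion with and without the inhibitor shared no arrays. Across the 11785 genes, which are not independent replicates, the fold changes correlated at r = 0.59, against 0.00 in simulated unchanged groups. Both comparisons called 758 genes higher and 752 lower, where independent lists would share 207 and 195, and 97 genes were called in opposite directions. The effects of the inhibitor in WT and in Wip1SH, also without shared arrays, correlated at r = 0.54, with 834 genes higher in both, 473 lower in both and 94 called in opposite directions. Independent lists would share 261 and 107. For depletion under the inhibitor, 506 genes were higher and 783 lower with array medians equal over all probes, and 1183 genes passed with the covariate.

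With both depletion and inhibitor, compared with untreated WT, expression differed in 4791 genes, 2774 higher and 2017 lower, of which 260 differed at least 2-fold. FGFR3 rose by 3.22 ± 0.09 (SE; adjusted p = 2.71e-09), although its dimmer probe was at -0.18. SNORA71C was at least 4.09-fold higher and PPIL6 at least 2.37-fold higher, ABTB1 rose by 2.14 ± 0.16, and HMOX1, the heme oxygenase of the oxidative stress response, by 1.94 ± 0.07. CLPTM1 fell by 3.65 ± 0.11, SLC1A3 fell by 2.88 ± 0.09, TGM2, a transglutaminase gene, by 2.54 ± 0.09, SUSD2 by 2.51 ± 0.10 and CHPF by 2.17 ± 0.10. Of the 3 Wip1SH+ATMi arrays, SLC1A3 was above background on 1 and SUSD2 on 2, which limits those falls. Mitosis genes fell (26 of 35, 27 when adjusted over the list alone; adjusted p = 8.18e-11), with a median of -0.42 that became 0.02 with array medians equal over all probes, where the median of the tested genes was 0.40. KIF20A fell by 1.06 ± 0.11, KIF23 by 0.92 ± 0.10, CDC20 by 0.81 ± 0.09 and DLGAP5 by 0.66 ± 0.07. MYC-responsive growth genes fell (15 lower and 1 higher of 25, or 18 and 1 when adjusted over the list alone; median -0.32, 0.09 under that scaling; adjusted p = 4.72e-06), as did MYC, by 0.58 ± 0.09, PPAN, by 0.81 ± 0.10, BOP1, by 0.60 ± 0.08, NOP56, by 0.59 ± 0.08, and NOLC1, by 0.55 ± 0.07. Genes of the ATF4 and unfolded protein response rose (18 higher and 1 lower of 26, also when adjusted over the list alone; median 0.40, adjusted p = 4.72e-06), with PPP1R15A up by 1.40 ± 0.09, TRIB3 by 1.20 ± 0.07, DDIT4 by 0.90 ± 0.08 and STC2 by 0.87 ± 0.06. Wnt targets and intestinal stem cell markers fell by the preset test (7 of 12, also when adjusted over the list alone; adjusted p = 0.00238), with adjusted p = 0.0935 with an estimated correlation. DKK1 fell by 1.01 ± 0.08, RNF43 by 0.63 ± 0.12 and AXIN2 by 0.54 ± 0.10.

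The p53 targets had 14 genes higher and 7 lower of 32 (also when adjusted over the list alone; adjusted p = 0.198), with GADD45A up by 1.00 ± 0.08, SESN1 up by 0.55 ± 0.08 and SFN down by 0.93 ± 0.08. DNA replication genes had 1 higher and 6 lower of 30 (also when adjusted over the list alone; median -0.05, adjusted p = 0.142). MACROH2A2 rose by 0.31 ± 0.07, KLF4 by 0.80 ± 0.08, BARD1 by 0.84 ± 0.12 and RING1 by 0.56 ± 0.08, while DAXX fell by 0.62 ± 0.07, MBD1 by 0.74 ± 0.11, UHRF1 by 0.63 ± 0.08, PODXL by 0.51 ± 0.09 and H3-3B by 0.39 ± 0.07. DNMT1 fell by 0.25 ± 0.07 and MDM2 by 0.54 ± 0.16, calls lost under 6 and 4 of 24 alternatives, for DNMT1 without WT replicate 3 or Wip1SH+ATMi replicates 2 or 3 and for MDM2 without Wip1SH+ATMi replicate 3 among them. MACROH2A1 (-0.09 ± 0.07, adjusted p = 0.346, with dimmer detected probes at -0.29 and 0.20), DNMT3B (-0.14 ± 0.08, adjusted p = 0.212) and CDKN1A (0.02 ± 0.08, adjusted p = 0.875, with the dimmer probe at -0.04) did not pass. The control genes passed with the covariate only (adjusted p = 0.0172). The calls split into 6361 higher and 386 lower genes with array medians equal over all probes, and into 2419 and 2708 with medians equal over the tested probes. With the covariate 40 genes passed, and 33 of the 43 named genes past the threshold lost their call, PPM1D among them (-1.29, adjusted p = 0.102).

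The interaction tested whether the inhibitor acted differently in Wip1SH than in WT, as the difference of its log2 fold changes (Wip1SH minus WT). It passed in 367 genes, 224 with a higher and 143 with a lower value, and in 36 the difference was at least 1 on the log2 scale. The p53 targets were lower by a median of 0.24 (median interaction -0.24; 5 lower and 1 higher of 32, or 6 and 1 when adjusted over the list alone; adjusted p = 0.00041). Their largest differences were -0.89 ± 0.12 (SE) for TP53I3, -0.80 ± 0.14 for GDF15, -0.75 ± 0.13 for TP53INP1 and -0.64 ± 0.11 for GADD45A. For the last of these genes, part came from rises in WT, where GDF15 rose as given above. TP53INP1 was at 10.19 to 10.45 on the WT and 10.75 to 10.85 on the WT+ATMi arrays. GADD45A was at 10.67 to 10.83 and 10.95 to 11.12. The list score moved less in WT, from -0.13 to -0.11, than in Wip1SH, from 0.22 to 0.01. DNA replication genes had a median of 0.28 (3 higher of 30, 12 when adjusted over the list alone; adjusted p = 7.58e-06), or -0.01 with array medians equal over all probes, where the median of the tested genes was -0.28. MCM5 had 0.64 ± 0.13, a call lost without WT+ATMi replicate 1 or 3 and without Wip1SH+ATMi replicate 2. RFC5 had 0.46 ± 0.10 and MCM7 0.42 ± 0.09, calls lost without any 1 array except, for RFC5, WT, Wip1SH or Wip1SH+ATMi replicate 2 and, for MCM7, WT+ATMi or Wip1SH+ATMi replicate 1. NRF2 targets had a median of -0.20 (2 lower of 15, 4 when adjusted over the list alone; adjusted p = 0.000478), with AKR1B10 at -0.91 ± 0.10 and NQO1 at -0.58 ± 0.10. These 3 lists passed with an estimated correlation too, each with an adjusted p of 0.0208. The remaining lists past the preset test did not, namely Wnt targets and intestinal stem cell markers (median -0.30, 2 lower of 12, also when adjusted over the list alone; adjusted p = 0.00584, and adjusted p = 0.0859 with an estimated correlation), cholesterol and fatty acid synthesis (median -0.19, 0 of 17 past the threshold and 4 lower when adjusted over the list alone; adjusted p = 0.0122, and adjusted p = 0.0774 with an estimated correlation) and DNA methylation (median 0.23, and -0.06 with array medians equal over all probes; 3 higher of 11, or 4 higher and 1 lower when adjusted over the list alone; adjusted p = 0.0172, and adjusted p = 0.0774 with an estimated correlation). In the Wnt list NKD1 was at -0.90 ± 0.14 and SOX9 at -0.61 ± 0.13 (lost without any 1 array except WT replicate 2, WT+ATMi replicates 1 and 2 and Wip1SH+ATMi replicate 3), and in the DNA methylation list MBD4 at 0.86 ± 0.14, UHRF1 at 0.54 ± 0.11 (lost without any 1 array except WT replicates 2 and 3, Wip1SH replicate 1 and Wip1SH+ATMi replicate 3) and DNMT3B at 0.54 ± 0.12. The DNMT3B call (adjusted p = 0.0319) was lost under 13 of 23 alternatives, among them every left-out array except Wip1SH replicate 3 and Wip1SH+ATMi replicate 2.

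The mitosis list had no interaction past the threshold (median 0.01, adjusted p = 0.667), nor had the ATF4 and unfolded protein response list (median -0.06, adjusted p = 0.896). The genes with the highest interaction were ACSF3 (1.34 ± 0.32, SE; adjusted p = 0.0477), RNA18SN5 (1.30 ± 0.26), LMOD3 (1.27 ± 0.11), SNORA57 (1.23 ± 0.22) and TXNDC2 (1.19 ± 0.24), of which LMOD3 and SNORA57 passed under all 23 alternatives, while ACSF3 lost its call without any 1 array except WT or Wip1SH+ATMi replicate 1. RNA18SN5 lost it without WT replicate 3, WT+ATMi replicates 2 or 3, Wip1SH replicate 1 or Wip1SH+ATMi replicate 3, and TXNDC2 without WT+ATMi replicate 3, Wip1SH replicate 3 or Wip1SH+ATMi replicate 2. The lowest were FOS (-1.47 ± 0.28), WFDC2 (-1.37 ± 0.19), MYH16 (-1.31 ± 0.22), LCE1A (-1.29 ± 0.20) and AKR1B15 (-1.16 ± 0.18), which passed under every alternative that measured them. Interaction values short of the threshold were PPM1D -0.18 ± 0.15, ATM -0.49 ± 0.25, MACROH2A1 0.14 ± 0.11, MACROH2A2 0.02 ± 0.10, MYC 0.08 ± 0.12, DNMT1 0.05 ± 0.10, CDKN1A -0.29 ± 0.11 and MDM2 0.07 ± 0.22, with adjusted p-values of 0.186 to 0.925. The CDKN1A value is that of the probe near the top of the scale, and the dimmer CDKN1A probe, detected on all 12 arrays but not tested, had an interaction of -0.58. The count fell to 235 without WT replicate 3, 218 and 164 without WT+ATMi replicates 1 and 3, 183 and 220 without Wip1SH replicates 1 and 3, and 241, 219 and 234 without Wip1SH+ATMi replicates 1, 2 and 3. It was 231 with the covariate and 572 without background correction, and the calls split into 296 higher and 104 lower with array medians equal over the tested probes and into 11 and 256 with medians equal over all probes.

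Several lists passed in none of the 6 comparisons. Their lowest adjusted p-values were 0.0952 for the interferon response, 0.107 for hypoxia and glycolysis, 0.151 for NF-kB and inflammatory cytokines, 0.165 for cancer-testis and germline genes, 0.233 for both DNA damage signalling and repair and the histone variant and Polycomb list, 0.624 for intestinal differentiation and 0.664 for lysosome and autophagy. Markers of other cell types (fibroblasts, leukocytes, endothelium, erythroid cells and hepatocytes) had 5 measured genes and a lowest adjusted p of 0.459. The interferon response list, which fell short for the inhibitor in Wip1SH (7 lower and 2 higher of 19), passed there with array medians equal over all probes (adjusted p = 0.0335) and without Wip1SH+ATMi replicate 1 (adjusted p = 0.0465), and it passed for Wip1SH+ATMi against WT with those equal medians (adjusted p = 0.0251). The NF-kB list passed for depletion under the inhibitor with the stricter detection filter (adjusted p = 0.0481) and the hypoxia list with the mean of probes (adjusted p = 0.0409).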

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

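The tests on the 6 genes with fitted fold changes below that of PPM1D (need for ATM activity, spread between arrays, and brightness by detection), the brightness test of the DNA replication list and the relabelling test that divides an interaction by its standard error were chosen only after the result was seen. With 3 arrays per group, single arrays were not tested for lying far from the others.

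The effect of the inhibitor differed between Wip1SH and WT by a test of the difference itself, the interaction, in 367 genes. The lists past that test had median interactions of -0.24 for p53 targets, 0.28 for DNA replication, 0.23 for DNA methylation, -0.30 for Wnt targets and intestinal stem cell markers, -0.19 for cholesterol and fatty acid synthesis and -0.20 for NRF2 targets. With an estimated correlation the DNA methylation (adjusted p = 0.0774), Wnt (adjusted p = 0.0859) and cholesterol (adjusted p = 0.0774) lists did not pass. With array medians equal over all probes, the medians for DNA replication and DNA methylation were -0.01 and -0.06, against a median of -0.28 over the tested genes. The genes with the largest interactions were ACSF3 (1.34), RNA18SN5 (1.30), LMOD3 (1.27), SNORA57 (1.23) and TXNDC2 (1.19) in one direction and FOS (-1.47), WFDC2 (-1.37), MYH16 (-1.31), LCE1A (-1.29) and AKR1B15 (-1.16) in the other. ACSF3 lost its call without any 1 array except WT or Wip1SH+ATMi replicate 1, RNA18SN5 without any 1 of 5 arrays (WT 3, WT+ATMi 2 and 3, Wip1SH 1, Wip1SH+ATMi 3) and TXNDC2 without any 1 of 3 (WT+ATMi 3, Wip1SH 3, Wip1SH+ATMi 2). The count of 367 was 164 without WT+ATMi replicate 3 and 183 to 241 without any 1 of 7 others (WT 3, WT+ATMi 1, Wip1SH 1 and 3, Wip1SH+ATMi 1, 2 and 3).

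Among 100 drawn relabellings of treatment within each genotype, 1, the real one, gave as many as 367 genes. The highest of the others gave 348. Relabelling mixes treated and untreated arrays, so the inhibitor's effect shared by both genotypes enters the spread within groups or the interaction. These counts therefore decide nothing about chance. For the differences of groups the 6 arrays allow 10 splits, too few for a share under 0.05, and in each comparison 1 split, the real one, gave as many genes. The real counts were 3794, 3002, 2750, 2495 and 4791 for Wip1SH against WT, WT+ATMi against WT, Wip1SH+ATMi against Wip1SH, Wip1SH+ATMi against WT+ATMi and Wip1SH+ATMi against WT. The highest counts of the other splits, by limma, were 0, 0, 0, 0 and 2, with 716, 845, 632, 575 and 717 genes at an unadjusted p under 0.05.

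The first pattern weighed is that p53 targets rose and DNA replication genes fell in Wip1SH, and both shifted back as lists under the inhibitor. For p53 these were largely different genes: 4 of the 15 that had risen fell again. SFN, TP53I3 and PLK2, named above for their falls under the inhibitor, were not among those 15. Of the 17 DNA replication genes that had fallen, 13 rose again. Array brightness differed between the groups, but the slope of the p53 score on the number of detected probes within groups predicted a share of 0.0331 ± 0.0368 (SE) of the p53 interaction. For the DNA replication list the share was 0.0398 ± 0.0419 (SE). With detected probes as a covariate the median interactions were -0.23 for p53 and 0.27 for DNA replication, and both lists passed. These values argue against brightness as the main cause of the interaction of either list. Brightness differences largely cancel in the interaction (-358 detected probes, against 1524 for WT+ATMi minus WT). No share was computed for the shift on depletion or for the return under the inhibitor alone. Both lists passed in those comparisons too with the covariate. Relabelling treatments within genotypes gave a p53 interaction as large in 12 of 400 cases (exact permutation p = 0.03, two-sided). That relabelling supposes no effect of the inhibitor in either genotype. The p53 score fell from 0.22 in Wip1SH to 0.01 in Wip1SH+ATMi, so the test does not bear on the interaction alone. For the DNA replication list 40 of 400 were as large (exact permutation p = 0.1), but the inhibitor raised that score in both genotypes, so relabelling the WT arrays can only widen the difference and this test decides nothing. With the interaction divided by its standard error within the relabelled groups, 10 of 400 were as large for DNA replication (exact permutation p = 0.025). For p53, 14 of 400 were (exact permutation p = 0.035), with the same limit as the p53 test above. For DNA replication the rise shared by both genotypes enters the standard error of mixed groups, so this test decides nothing there either. With array medians equal over all probes, the return under the inhibitor had a median of -0.04 for p53 targets, where the median of the tested genes was 0.15, and DNA replication had the median interaction of -0.01 given above, where it was -0.28. Both lists passed there (adjusted p = 0.0039 and 0.00674), so the shifts relative to the other genes do not rest on the quantile normalization, while their absolute size does depend on it. The biological explanation in the design is that these shifts depend on ATM activity in cells with little Wip1. The p53 list values do not contradict it, as a hypothesis found and tested on the same data. The interactions of GDF15, TP53INP1 and GADD45A came partly from rises in WT, which it does not cover. Effects of the inhibitor on other kinases and a clonal difference between the lines were not tested.

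The second pattern is that CLPTM1, SLC1A3, SUSD2, IL32, TESC and VSNL1 had lower fitted fold changes in Wip1SH than PPM1D, the target. For IL32 this rests on a fit against an undetected probe, and the bound printed for it does not reach PPM1D. For VSNL1 it rests on the tested probe, since the other detected one was at -1.38, against -1.66 for PPM1D. CLPTM1, TESC and VSNL1 were detected on every array. For these 3 genes brightness predicted a mean share of -0.0426 ± 0.0372 (SE) of the fall, which argues against it as the main cause. On the arrays with the inhibitor, which did not enter the choice of the genes, the largest SD within a group was at most 0.146 of the fall, so disagreement between arrays does not account for them. Their fall with the inhibitor over the fall without it had a median of 1.18 and a lowest value of 1.06. This argues against a need for ATM activity over the 3 days of inhibition, and says nothing about earlier times. SLC1A3, SUSD2 and IL32 were near background on some arrays, which limits their falls. Their values of 0.0167 ± 0.0317 (SE) for brightness, 0.129 for the SD and 0.885 for the median ratio exclude nothing. What stays open is an effect of Wip1 that does not need ATM activity over those days, an effect of the hairpin on other transcripts, or a clonal difference between the lines. The sequence of the hairpin was not used here, and these were not tested.

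The third pattern is that more genes were higher than lower in WT+ATMi than in WT, 1820 against 1182. The share of calls that were higher ranged from 0.431 to 0.977 over the background corrections and normalizations, so the excess may come from the normalization. Brightness cannot be told apart from the treatment here, because the WT arrays had the fewest detected probes. Across genes, which are not independent replicates, the slope on detected probes within groups correlated with the fold change at r = 0.134, or 0.0489 to 0.147 without any 1 array. A true excess of raised transcripts stays open too.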

How the results depend on the processing

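Equal array medians over the tested probes and the covariate for detected probes were chosen only after the result was seen. The slide block was not run, because no slide is named for the arrays. Unless a value shows it, the cause was not tested.

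Across the 12 fits without 1 array, the counts ranged from 2835 to 3850 for Wip1SH against WT, 2073 to 3075 for WT+ATMi against WT, 1890 to 2772 for Wip1SH+ATMi against Wip1SH, 1752 to 2529 for Wip1SH+ATMi against WT+ATMi, 3965 to 4733 for Wip1SH+ATMi against WT and 164 to 321 for the interaction. The interaction was lowest without WT+ATMi replicate 3, with 183 without Wip1SH replicate 1, 218 without WT+ATMi replicate 1, 219 without Wip1SH+ATMi replicate 2, 220 without Wip1SH replicate 3 and 234 to 241 without WT replicate 3 or Wip1SH+ATMi replicates 1 or 3. The genes changed back numbered 517 to 762, lowest without Wip1SH replicate 1, the lists past the test 30 to 32, and the correlations were 0.557 to 0.606 for depletion and 0.505 to 0.552 for the inhibitor.

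Replicate numbers pair the arrays weakly at most: residuals of arrays with the same number correlated at -0.0819 to 0.141, with 3 of 18 pairs over 0.1, and of other arrays at -0.138 to 0.151, although 9 of 12 arrays correlated best with one of their own number. With the number as a replicate block, the counts were 3709, 2910, 2615, 2368, 4734 and 295 in the order above, with 31 lists past the test and 744 genes changed back. The list lost was NRF2 targets in Wip1SH against WT (adjusted p = 0.0666).

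With array medians equal over all probes, 7206 genes passed in WT+ATMi against WT, 1289 in Wip1SH+ATMi against WT+ATMi, and 264 were changed back. This scaling moved the median of the tested genes to 0.24, 0.43, 0.15, -0.01, 0.40 and -0.28. In WT+ATMi against WT, 9 genes that had fallen then had fold changes above 0 but below that shift: MACROH2A1 0.19, MYC 0.091, DNMT3B 0.17, TDG 0.0351, UHRF1 0.18, DAXX 0.12, CAD 0.0887, NOLC1 0.22 and NOP56 0.11. In Wip1SH+ATMi against WT the same held for DNMT1 (0.16) and H3-3B (0.0784). With medians equal over the tested probes, 5 of 283 calls of named genes were lost and none reversed.

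With the covariate, 886, 33, 159, 1183, 40 and 231 genes passed, 30 were changed back and the inhibitor's effects correlated at 0.655. The fold changes moved less than the counts: PPM1D in Wip1SH against WT was at -1.54 in place of -1.66, and in Wip1SH+ATMi against WT at -1.29 in place of -1.55. The number of detected probes differs between the groups, so the covariate takes up part of what separates them.

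Without background correction 572 genes passed in the interaction and the effects of depletion correlated at 0.638, or 0.634 with the offset of 50. Without the detection filter the correlations were 0.534 and 0.492, and with the stricter filter 0.638 and 0.589. With the fold threshold 115, 97, 66, 85, 260 and 36 genes passed and 6 were changed back, by the construction of that threshold. With an estimated correlation 19 of the 32 lists passed. With the mean of probes, PRKDC in Wip1SH+ATMi against Wip1SH was at -0.0077. The deposited log2 values moved no count.

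Of 283 calls of named genes, 150 passed under every alternative that measured them (the fold threshold aside), 133 were lost under at least 1, and 12 of these reversed.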

Other observations

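All tests of lists in this part were chosen only after the result was seen.

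Replication-dependent histone genes, as a list drawn up after the fold changes were seen, rose in Wip1SH against WT (14 higher and 1 lower of 25, median 0.45, adjusted p = 6.6e-07, limma camera) and in Wip1SH+ATMi against WT+ATMi (8 higher, none lower, median 0.34, adjusted p = 0.000476). The list also passed in Wip1SH+ATMi against WT (10 higher and 2 lower, adjusted p = 0.01) and, downward, in the interaction (median -0.19, adjusted p = 0.00829), with no single gene past the threshold there. In WT+ATMi against WT (adjusted p = 0.429) and Wip1SH+ATMi against Wip1SH (adjusted p = 0.278) it did not pass. Immediate-early and ERK feedback genes rose in Wip1SH against WT (12 higher and 1 lower of 18, median 0.33, adjusted p = 0.000545) and in Wip1SH+ATMi against WT (9 higher and 2 lower, adjusted p = 0.0177). In Wip1SH+ATMi against WT+ATMi (5 higher and 1 lower, adjusted p = 0.0557) and in the interaction (adjusted p = 0.0663) that list did not pass, so a dependence on the inhibitor is not shown. Cytoplasmic tRNA synthetases did not pass in Wip1SH against WT (4 higher and 3 lower of 18, or 6 and 4 when adjusted over the list alone; adjusted p = 0.811), and among those lower IARS1, with 1 detected probe, fell by 1.05 there. These lists were chosen from the same data, so the p-values describe the data and test no independent idea.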
